A study of Mus musculus with 6 samples.

How the data were processed

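Chromatin from mature CD4+ and mature CD8+ T cells of the thymus of C57BL/6 mice was cut to mononucleosomes with micrococcal nuclease and precipitated with rabbit polyclonal antibodies against H3K4me3 or H3K36me3, per the labels. H3K4me3 is a histone mark found at active promoters and H3K36me3 a mark found over transcribed gene bodies. An input without antibody was sequenced for each cell type. The 6 libraries form 6 groups of 1 library each, so no value has a replicate and no p-value is given.

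The deposited values are the start and end positions of aligned reads, 1 read per line, with no strand and no score. Every read was 33 bp wide. The positions refer to mouse build mm9, per the submitters' processing notes. The aligner, its handling of reads with several matches and any removal of repeated reads are not given in the sources used here. Coordinates are printed 1-based in mm9, and an offset of 1 bp in the deposited starts was not excluded.

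Reads on chromosomes 1 to 19, X and Y were kept, which left between 98.3% and 99.8% of each library. A read was counted in the window that held its midpoint. No gene annotation of mm9 was used here, so 2 kb windows took the place of promoters for H3K4me3 and 10 kb windows the place of gene bodies for H3K36me3, and no gene names are given. The 17 gene lists with 257 symbols that were fixed for the study were not applied for the same reason. The rules, thresholds and most alternatives were set before the data were examined.

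A window counted as enriched when it held at least 20 reads and at least 4 times (H3K4me3) or 2 times (H3K36me3) the RPM (reads scaled to library size) of the input of the same cell type, with input set to at least 3 reads. The background of this rule was measured by treating the input of the other cell type as the precipitated library. Background level was measured in 804166 windows of 2 kb that lay at least 10 kb from any window with more than 9 reads of either mark.

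CD4 and CD8 reads were compared in windows enriched in either cell type. The log2 ratio was centred on its median over windows enriched in both. A window counted as different when the fold was at least 2 and the exact (Clopper-Pearson, conditional on the sum) 99.9% interval excluded 1, and printed intervals are 95% intervals of the same kind. These intervals cover counting error only and compare the 2 libraries, not the conditions, and reads without molecular identifiers are not independent molecules. A fold against 0 reads was computed against a floor of 3 reads per library. Shares have exact binomial 95% intervals.

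H3K4me3 domains were runs of 200 bp bins with at least 4 times the input, joined over gaps of up to 400 bp, with at least 20 reads. Input was set to at least 3 reads per bin. Most bins held fewer input reads, so there the rule acted as a nearly fixed cutoff of reads per bin. The named windows were the 5 of each direction and mark with the largest lower 95% bound of the fold, adjacent windows taken once, and the named domains were the 5 widest of each cell type. Other regions in the text were chosen after their values were seen. The 2 marks were compared over 10 kb windows by Pearson and Spearman correlation on log2 ratios with 0.5 reads added, and windows are not independent replicates.

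The difference rule was tested on simulated data with Poisson counts from the real means and 200 changed windows per mark. Of 100 windows changed 2.5-fold it recovered 97.0% for H3K4me3 and 95.0% for H3K36me3, and of 100 changed 4-fold it recovered 100% for both marks. It called 5 of 23705 unchanged H3K4me3 windows and 7 of 30822 unchanged H3K36me3 windows. These simulations hold no variation between libraries beyond counting. All 100 planted domains of each width, 1000, 2000 and 4000 bp, were recovered to within 400 bp. They were flat stretches with reads far above the cutoff, so weaker or uneven domains were not tested.

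Alternatives were 1 read per position, stricter folds, at least 50 reads, pooled inputs, other scalings, input subtraction, a thinned deeper library and wider gaps. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.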

Results

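H3K4me3 and H3K36me3 were mapped in mature CD4+ and CD8+ T cells from mouse thymus, with 1 library per mark and cell type and 1 input per cell type. The H3K4me3 libraries held 10784658 reads in CD4 cells and 12136610 in CD8 cells. The H3K36me3 libraries held 6844546 and 6860729 reads, and the inputs 10237817 and 10030065 reads. Distinct start positions made up 54.4% of the reads of the CD4 H3K4me3 library and 31.5% of those of the CD8 H3K4me3 library, against 91.2% and 91.8% for H3K36me3 and 97.2% and 97.6% for the inputs. Away from enriched regions the CD4 H3K4me3 library had 19.1% of the input level and the CD8 H3K4me3 library 1.20%, while the H3K36me3 libraries had 31.6% in CD4 and 32.5% in CD8.

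The first question was where each mark lay in each cell type. H3K4me3 was enriched in 22953 windows of 2 kb in CD4 cells and 21037 in CD8 cells. These windows took 76.3% of the CD4 reads and 96.7% of the CD8 reads, and 1.49% and 1.15% of the matching input reads. The median fold over input was 31.8 in CD4 and 52.9 in CD8. With the other cell type's input in place of the precipitate, 229 windows passed against the CD4 input and 140 against the CD8 input.

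H3K36me3 was enriched in 27245 windows of 10 kb in CD4 cells and 27058 in CD8 cells, which took 58.5% and 59.1% of the reads. Its median fold over input was 4.10 in CD4 and 4.25 in CD8. The other input passed in 994 and 972 windows. Chromosome 11 had the highest share of H3K36me3 windows in both cell types, 17.3% in CD4 and 16.8% in CD8, and chromosome X the lowest, 6.16% and 6.82%. A few windows with large numbers of input reads are among those counted. The window of 2 kb at chromosome 2:98506001-98508000 held 131237 CD4 and 117044 CD8 H3K36me3 reads.

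Most enriched windows were shared between the cell types. For H3K4me3, 19376 windows were enriched in both, which is 84.4% of the CD4 windows (95% interval 83.9 to 84.9) and 92.1% of the CD8 windows (91.7 to 92.5). For H3K36me3, 24050 windows were enriched in both, 88.3% of the CD4 windows (87.9 to 88.7) and 88.9% of the CD8 windows (88.5 to 89.3).

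The second question was which regions differed between CD4 and CD8 cells. H3K4me3 reads were higher in CD4 in 6152 windows and higher in CD8 in 1250 of the 24614 windows tested. Between the inputs the same fold and interval, centred on total reads in place of the median, called 5 and 0 windows. The inputs had a median of 6 reads in CD4 and 5 in CD8 per enriched window, far below the depth of H3K4me3. The input count is therefore no control for the calls. CD4 had 83.1% of the different H3K4me3 windows. Scaling to total reads shifted every log2 ratio by 0.40 and gave 4457 windows higher in CD4 and 3854 higher in CD8, a CD4 share of 53.6%. A centre that followed the mean read count gave 5026 and 1869 windows, a CD4 share of 72.9%. The folds below are relative to the median. With 1 library per group, the counts compare libraries and have no replicate check.

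The 5 named H3K4me3 windows higher in CD4 held between 509 and 1672 CD4 reads and at most 7 CD8 reads. Chromosome 3:89190001-89192000 had 1672 CD4 and 4 CD8 reads, a 624-fold difference (95% interval 243 to 2294). With 1 read kept per position its log2 ratio was 7.49 against 9.29, below that interval. Chromosome 2:43604001-43606000 had 763 and 2 reads, a ratio of 569.8 (157 to 4714). Chromosome 1:60804001-60806000 had 1499 and 7 reads, a 319.9-fold difference (155 to 797). Chromosome X:54466001-54468000 had 657 and 2 reads, a ratio of 491 (135 to 4060). Chromosome 17:51968001-51970000 had 509 and 2 reads, a ratio of 380.1 (105 to 3147). It lies within a CD4 domain at chromosome 17:51961401-51973800 that held 4472 CD4 and 3349 CD8 reads and overlapped 4 CD8 domains. The locus is thus not marked in CD4 only.

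The 5 named H3K4me3 windows higher in CD8 included a pair on chromosome 6 that lay 20 kb apart. Chromosome 6:71304001-71306000 had 347 CD8 reads and 0 CD4 reads, 77.4-fold higher in CD8 with CD4 set to the floor of 3 reads, and a lower 95% bound of 62.6. Chromosome 6:71324001-71326000 had 1544 CD8 and 20 CD4 reads, a 51.7-fold difference (33.4 to 84.9). Chromosome 4:134678001-134680000 had 1448 and 10 reads, a 96.9-fold difference (52.6 to 203). Chromosome 17:84246001-84248000 had 591 and 5 reads, a 79.1-fold difference (33.7 to 245). Chromosome 7:53652001-53654000 had 412 and 3 reads, a ratio of 92.0 (31.2 to 448).

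**Figure D1:**
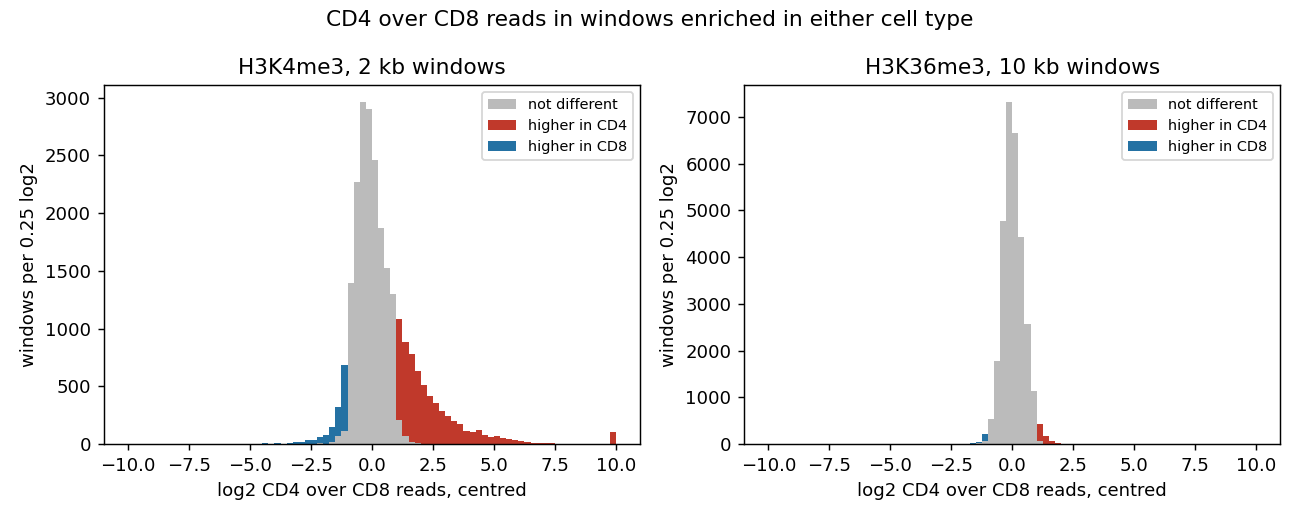
Windows per 0.25 log2 (vertical axis) by centred log2 ratio of CD4 over CD8 reads (horizontal axis) for H3K4me3 in 2 kb windows and H3K36me3 in 10 kb windows, with windows higher in CD4 in red, higher in CD8 in blue and the rest in grey, and ratios beyond 10 placed in the end bars. H3K4me3 ratios spread more widely than H3K36me3 ratios, with a standard deviation over windows enriched in both of 0.89 against 0.38.

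Most different windows stood alone. Windows higher in CD4 formed 5243 separate regions for H3K4me3, 679 of them of 2 or more windows, and windows higher in CD8 formed 1117, of which 116 had 2 or more windows. The longest CD4 region, chromosome 14:54778001-54830000, spanned 52.0 kb with 8049 CD4 and 2561 CD8 reads, a log2 ratio of 2.23. The longest CD8 region, chromosome 6:71272001-71284000, spanned 12 kb with 383 CD4 and 3027 CD8 reads, a log2 ratio of -2.40.

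**Figure D2:**
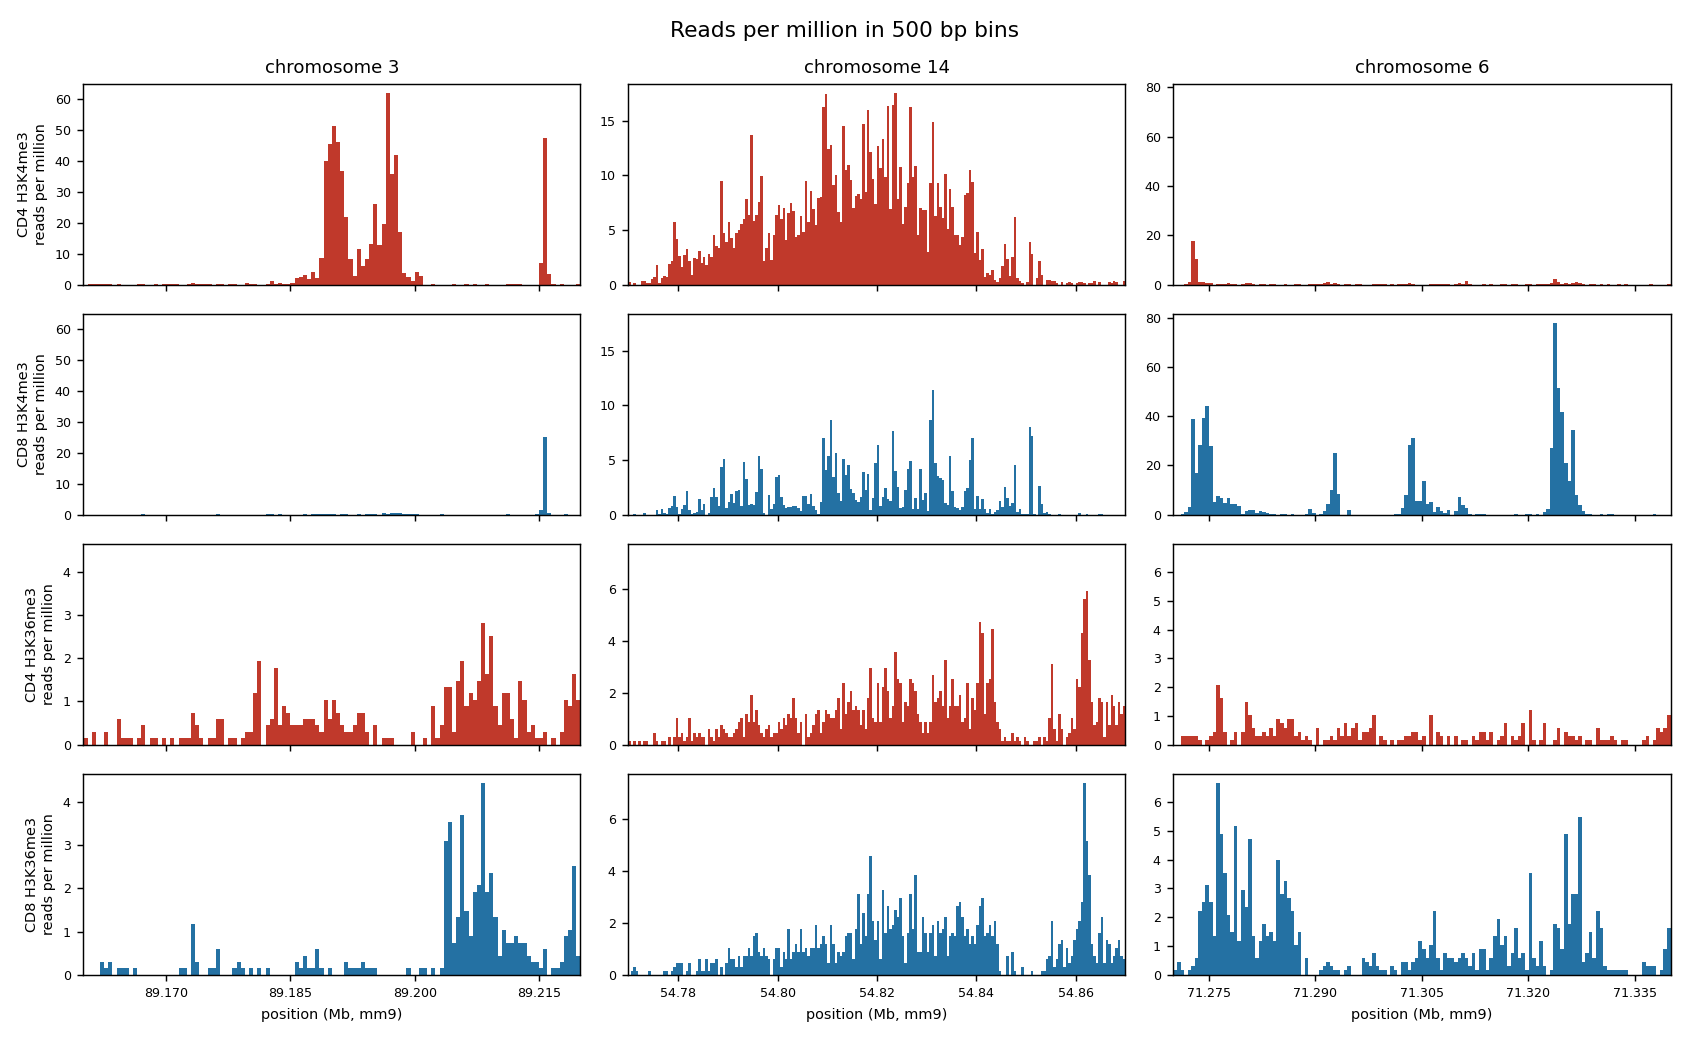
RPM (reads scaled to library size) in 500 bp bins (vertical axis) along chromosome 3, chromosome 14 and chromosome 6 (horizontal axis, Mb in mm9) for H3K4me3 and H3K36me3 in CD4 (red) and CD8 (blue), with 1 library per panel. The chromosome 3 domain had 5616 CD4 and 51 CD8 H3K4me3 reads.

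H3K36me3 differed in fewer windows. It was higher in CD4 in 628 windows and higher in CD8 in 254 of 30253 windows tested, a CD4 share of 71.2%. Between the inputs the same fold and interval, centred on total reads, called 24 and 13 windows. The window at chromosome 11:72950001-72960000 had 148 CD8 and 11 CD4 reads, a 13.1-fold difference (7.09 to 26.7), and lay in a region of 60 kb with a log2 ratio of -2.57. Chromosome 2:126190001-126200000 had 151 CD8 and 19 CD4 reads, a 7.71-fold difference (4.77 to 13.2), within a region of 150 kb that held 2791 CD8 and 913 CD4 reads. Chromosome 6:71320001-71330000 had 227 and 36 reads, a 6.12-fold difference (4.29 to 8.96). Chromosome 8:97460001-97470000 had 134 and 17 reads, a 7.65-fold difference (4.60 to 13.5). Chromosome X:38940001-38950000 had 61 and 5 reads, an 11.8-fold difference with an interval from 4.80 to 37.8.

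The 5 named H3K36me3 windows higher in CD4 held between 26 and 165 CD4 reads. Chromosome 3:41040001-41050000 had 83 CD4 and 6 CD8 reads, a 14.3-fold difference (6.28 to 39.97). Chromosome 12:103640001-103650000 had 63 and 6 reads, a 10.8-fold difference (4.71 to 30.6). Chromosome 9:70960001-70970000 had 26 and 1 reads, a ratio of 26.8 (4.40 to 1099). Chromosome 10:80670001-80680000 had 136 and 20 reads, a 7.01-fold difference (4.37 to 11.8). Chromosome 15:25730001-25740000 had 165 and 26 reads, a 6.54-fold difference (4.31 to 10.3).

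Domain width gave a second view of H3K4me3. CD4 cells had 15608 domains and CD8 cells 14871, with a median width of 1000 bp in each. Domains of 2 kb or wider numbered 2021 in CD4 and 1482 in CD8, or 2545 and 2402 with 1 read kept per position. Domains of 5 kb or wider numbered 100 in CD4 and 47 in CD8. Of the CD4 domains 87.4% (86.8 to 87.9) overlapped a CD8 domain, and 92.5% (92.0 to 92.9) of the CD8 domains overlapped a CD4 domain. Among domains of 1 kb or wider 98.8% overlapped in each direction, and 102 CD4 and 92 CD8 domains did not.

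The widest CD4 domain covered 42.8 kb at chromosome 14:54797601-54840400. It held 7804 CD4 and 2635 CD8 reads, a 4.42-fold difference (4.23 to 4.63), and 14 separate CD8 domains of at most 3 kb lay within or across it. A further CD4 domain of 10.8 kb at chromosome 14:54786201-54797000 was 3.47-fold higher in CD4 (3.14 to 3.83). The domain at chromosome 17:51961401-51973800 was 12.4 kb wide in CD4 and 1.99-fold higher (1.91 to 2.09). The CD4 domain at chromosome 3:89187601-89198800 was 11.2 kb wide, overlapped no CD8 domain and was 164.5-fold higher (125 to 221). The widest CD8 domain, 11.4 kb at chromosome 11:52086801-52098200, matched a CD4 domain of 11.6 kb, and CD4 reads were 1.90-fold higher (1.84 to 1.96).

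The other 4 wide CD8 domains differed by at most 2.54-fold between cell types. The domain at chromosome 4:149070001-149079600 was 9.6 kb wide and 1.17-fold higher in CD4 (1.12 to 1.22). The domain at chromosome 5:114274201-114283000 was 8.8 kb wide and 1.14-fold higher in CD8 (1.09 to 1.19). The domain at chromosome 11:99008601-99017000 was 8.4 kb wide and 2.54-fold higher in CD4 (2.43 to 2.66). The domain at chromosome 2:31932201-31940400 was 8.2 kb wide and 1.14-fold higher in CD4 (1.10 to 1.18). With total-read scaling these log2 ratios are lower by 0.40, so the CD4-higher ratios on chromosomes 4 and 2 turn to CD8-higher.

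The last question was how the 2 marks related to each other. H3K36me3 dipped to about the input level at H3K4me3 domains and on average rose on both sides of them. The input level still lies above the H3K36me3 background away from enriched regions, 31.6% of input in CD4 and 32.5% in CD8. Around 9337 domains of 1 kb or wider shared by both cell types, H3K36me3 was at 0.935 times the input in CD4 and 1.01 times in CD8 at 1 kb from the centre, and at 2.68 and 2.75 times at 11 kb. In 10 kb windows, both marks were enriched in 3582 CD4 windows and 3832 CD8 windows, 2.95 and 3.16 times the number for independent marks.

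**Figure D3:**
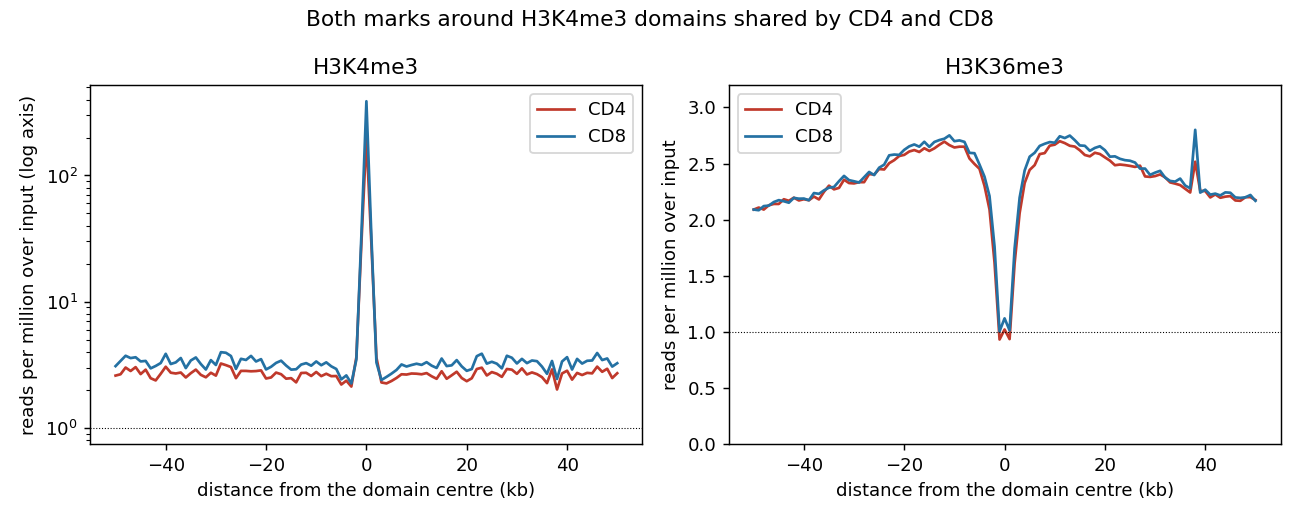
RPM over input (vertical axis, logarithmic for H3K4me3) against distance in kb from the centre of 9337 shared H3K4me3 domains (horizontal axis) for CD4 (red) and CD8 (blue). H3K36me3 falls to about the input level at the centre in both cell types, which is above its background of 31.6% (CD4) and 32.5% (CD8) of input. The H3K36me3 spike at 38 kb on the right side may come from 1 window with many input reads, which was not tested. That window is chromosome 9:35112001-35114000, with 36939 CD8 reads.

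Across windows the CD4 over CD8 ratios of the 2 marks were at most weakly correlated. Over 4526 windows of 10 kb enriched for both, Pearson's r was -0.00148 (95% interval -0.0306 to 0.0277) and Spearman's rho -0.0393. Domains 2-fold or more different in H3K4me3, 1 per 100 kb, were also split at 200 H3K36me3 reads. For those higher in CD4 Pearson's r was -0.104 below 200 reads and -0.132 from 200 on. For those higher in CD8 it was 0.201 and 0.0607. Of the H3K4me3 domains higher in CD4 62.0% had H3K36me3 ratios above 0 within 10 kb, of those higher in CD8 62.2% and of those not different 62.5%, so the base lies above 0, at a median of 0.12 for domains not different. The tails were less alike. In the same order, log2 ratios of at least 1 and of at most -1 numbered 97 and 5, 18 and 20, and 241 and 28. At the named windows the other mark was counted over the run of adjacent windows with 10 kb on each side. Against that base, 3 of the 5 H3K4me3 windows higher in CD4 had higher H3K36me3 ratios, 2 with intervals above it, and all 5 higher in CD8 had lower ratios, 3 with intervals below it. Of those 3, 2 are the pair on chromosome 6, whose counted stretches overlap and share reads. The H3K36me3 window at chromosome 6:71320001-71330000 lies at the same place. All 5 H3K36me3 windows higher in CD4 had H3K4me3 ratios above 0. In 3 of them at most 58 CD4 reads were counted, and the CD4 H3K4me3 library has the higher background, and the ratios on chromosomes 10 and 15, 0.28 and 0.27, are smaller than the shift of 0.40 from total-read scaling. Of the 5 H3K36me3 windows higher in CD8, 3 had lower and 2 had higher H3K4me3 in CD4. In the run that holds chromosome 6:71320001-71330000, H3K4me3 reads numbered 216 in CD4 and 5612 in CD8, a log2 ratio of -4.12 (-4.32 to -3.92). The run of chromosome 8:97460001-97470000 had 168 and 2415 H3K4me3 reads, a log2 ratio of -3.27 (-3.50 to -3.04), and that of chromosome 11:72950001-72960000 had 536 and 1981, a log2 ratio of -1.31 (-1.45 to -1.17). In the other direction, the run of chromosome 2:126190001-126200000 had 246 CD4 and 46 CD8 H3K4me3 reads (log2 interval 2.54 to 3.49), and that of chromosome X:38940001-38950000 had 17 and 0. The higher background of the CD4 H3K4me3 library, 0.202 reads per input read against 0.0146 in CD8, was not subtracted from these counts. It may make up part or all of the CD4 reads in these 2 runs, which was not tested. At chromosome 3:89190001-89192000 the run had 321 CD4 and 270 CD8 H3K36me3 reads, a log2 ratio of 0.29 (0.06 to 0.53), while the H3K36me3 region at chromosome 3:89180001-89200000 within it was called higher in CD4, with 135 and 28 reads and a log2 ratio of 2.31.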

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

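No explanation was tested for the values in this part, which were found in reads outside the chromosomes compared above. The reads lie on unplaced sequence or mitochondrial DNA, and each fold is in RPM over the input of the same cell type. H3K36me3 was 2.96-fold over input in CD4 and 3.29-fold in CD8 on unplaced sequence of no known chromosome. CD8 H3K4me3 was at 0.0433 times the input there and CD4 H3K4me3 at 0.696 times. The background of these 2 H3K4me3 libraries also differed, 1.20% of input in CD8 and 19.1% in CD4, so this gap cannot be read as a difference in the mark. On unplaced sequence of chromosome 1, H3K36me3 was 2.49-fold over input in CD4 and 2.48-fold in CD8. On unplaced sequence of chromosome 9, H3K4me3 was 4.34-fold over input in CD4 and 4.59-fold in CD8. H3K36me3 there was 2.09-fold over input in CD8 and 1.94-fold in CD4. CD8 H3K36me3 was 5.89-fold over input on mitochondrial DNA from 141 reads against 35 input reads, while CD4 H3K36me3 was at 0.629 times the input there. For H3K4me3 the order was reversed, with CD4 2.07-fold over input (316 against 145 reads) and CD8 at 0.0472 times (2 reads). The level on mitochondrial DNA thus differed between libraries for both marks and cannot be read as a difference in H3K36me3.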

How the results depend on the processing

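Input subtraction at the background level, scaling to reads in enriched windows, shifted windows, windows with many input reads left out, joined domains, and thinning for difference and domain counts were chosen after seeing the data. Of the 20 named windows, H3K36me3 at chromosome 9:70960001-70970000, with 26 CD4 reads and 1 CD8 read, was no longer tested at a minimum of 50 reads, and the 199 values that could be computed kept call and sign. For H3K4me3, the share of CD4 windows also enriched in CD8 was 83.4% with 1 read per position and 86.8% at 8-fold over input. The share of CD8 windows also enriched in CD4 was 93.2%, 90.3% and, with the deeper library thinned, 92.5%. H3K4me3 windows higher in CD8 numbered 3854 with total-read scaling and 379 at 3-fold, and joined domains gave 3539 higher in CD4 and 802 higher in CD8. For H3K36me3 at 3-fold over input, the shared part was 87.4% of CD4 and 86.2% of CD8 windows. H3K36me3 windows higher in CD4 and CD8 numbered 1192 and 483 with input subtracted at total reads, and 97 and 57 at 3-fold. The correlation of the marks was -0.0374 with 1 read per position. Domains of 2 kb or wider numbered 2545 in CD4 and 2402 in CD8 with 1 read per position, and 1172 in CD4 and 942 in CD8 at 8-fold over input. Stricter folds lower counts by construction, and for the other changes the cause was not tested. The other 97 values stayed within 1.5 times the count or inside the interval, or for median widths within 200 bp. Windows around gene starts, the last 50% of genes and the gene lists were not run, because no mm9 annotation was used. A minimum of 50 reads lowered the windows higher in CD4 to 4912 for H3K4me3 and 607 for H3K36me3.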

Other observations

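The patterns below were seen before they were tested. Keeping 1 read per position and total-read scaling were set before the data were seen, while background subtraction, scaling to reads in enriched windows and all tests on pile-ups and on H3K36me3 beside H3K4me3 were chosen afterwards. The spacing of 1 domain per 100 kb and the matching on H3K36me3 reads were added after first results without them. The test of H3K36me3 depth was replaced after its first result, so that it covers only domains with an H3K4me3 difference. The rule for the 2 to 4-fold domains was changed 2 times after its results were seen. For those higher in CD4, library differences were argued against without matching, were accepted under a first rule with matching, and are left open under the rule kept here. For the scaling to reads in enriched windows and the count of start positions, the outcome was predicted before it was computed.

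Part of the shared H3K4me3 domains had far more H3K36me3 reads on 1 side than on the other, and the side ahead was mostly the same in both cell types. Comparing the 20 kb on each side of the shared domains, 33.1% of 9206 domains in CD4 and 34.7% of 9147 in CD8 had at least 4 times more H3K36me3 reads on 1 side, against 0.204% and 0.236% for the inputs. Of the 3044 such CD4 domains, 3042 also had at least 50 reads in CD8, of which 3041 had the same side ahead in CD8, and 2700 were also at least 4-fold there.

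Several domains with many reads were found in 1 cell type only, chosen here after their values were seen. Chromosome 6:124835001-124838600 had 2015 CD4 and 14 CD8 H3K4me3 reads, a 215-fold difference (128 to 394), and chromosome 3:106587801-106593400 had 2152 and 51 reads, a 63.0-fold difference (47.8 to 84.9). In the other direction, chromosome 8:97447001-97449200 had 1774 CD8 and 31 CD4 reads, a 38.3-fold difference (26.9 to 56.6), and chromosome 7:50692401-50695000 had 1469 and 49 reads, a 20.1-fold difference (15.1 to 27.3).

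H3K4me3 windows higher in CD4 outnumbered those higher in CD8. Repeated reads in the CD8 library are argued against as the whole cause, since the CD4 share stayed at 83.0% with 1 read per position. Background reads in the CD4 library, at the level measured away from enriched regions, are also argued against as the whole cause, since the share was 82.9% with them subtracted. That subtraction changed the fold only, not the interval, and a higher background near enriched regions was not tested. The single calls were less stable than the CD4 share. With 1 read per position 4436 windows were higher in CD4 and 912 in CD8. Of the reported 6152 and 1250 windows, 3750 and 722 were among them. The choice of centre could account for much of the excess, as total-read scaling gave 53.6%. Totals include the CD4 background reads, however, and scaling to reads in enriched windows gave 79.6%. A centre that followed the mean read count gave 72.9%. Among windows enriched in both cell types, the excess was largest at low summed reads. At 41 to 271 reads the median log2 ratio was 0.46, with 1318 windows higher in CD4 and 218 in CD8. At 272 to 713 reads the counts were 1033 and 371, and at 714 to 1464 reads 474 and 244. At 1465 reads or more the median was -0.13, with 235 and 73. A further 3092 windows higher in CD4 were enriched in CD4 only. A difference between the cell types stays open and untested, because each cell type has 1 library.

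Pile-ups of reads on chromosome 2 were nearly missing from the CD8 H3K4me3 library, with 171 reads against 75764 in CD4. A lower background alone is argued against, since relative to background the CD4 level was 24.6 times the CD8 level. A cap on reads per start position is argued against by 35064 start positions elsewhere that held more reads than the most-read pile-up position. Removal of reads with many genomic matches may be the cause and cannot be told apart from other differences in handling, since the 71 reads left at the 10 main positions could have had a single match. No biological explanation was tested.

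Few H3K4me3 differences came with H3K36me3 differences, as counted within 10 kb of the domain. Too few H3K36me3 reads is argued against for domains with at least 200 of them, as 1.17% (0.539 to 2.22) of those 2-fold or more higher in CD4 and 2.66% (1.08 to 5.41) of those higher in CD8 had a 2-fold H3K36me3 difference the same way. That test covers the number of reads only. A narrow H3K36me3 difference can be diluted by the reads around it, and this was not tested. At chromosome 3 the log2 ratio was 2.31 inside a called region and 0.29 over the wider run. With 1 domain per 100 kb, 2.04% of domains 2 to 4-fold higher in CD4 (29 the same way, 6 opposite) compare with 1.13% (range 0.632 to 1.69) of domains under 2-fold matched on H3K36me3 reads, 1.44% (9 and 1) with 1.21% (0.480 to 2.08) at 4 to 8-fold and 2.17% (14 and 7) with 1.16% (0.466 to 2.02) at 8-fold or more. For CD8, 1.05% (7 and 7) compare with 0.551% (0.149 to 1.20) at 2 to 4-fold, 6.54% (7 and 0) with 0.574% (0 to 2.80) at 4 to 8-fold, and 9.68% (6 and 1, of 62, or 15.2% of 79 without spacing) with 0.598% (0 to 3.23) at 8-fold or more, a rise with size not seen for CD4. With 1 library per group and under the rule kept, differences between libraries and between cell types cannot be told apart for the 2 to 4-fold domains of either direction.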
